A study of Homo sapiens with 4 samples.

How the data were processed

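The series compared ATAC-seq of LNCaP cells given vehicle or GSK2879552. Libraries were made with a commercial Tn5 tagmentation enzyme, per the labels' protocols. The 4 samples are 2 lanes per condition, and the labels of both lanes name 1 peak list, so each list was taken to pool the lanes of its condition. The protocol text with the dose and time is the same for all samples, and the group of each sample was taken from its agent label. Nothing in the labels says that a condition had more than 1 culture.

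BWA 0.7.2, SAMtools 0.1.18 and MACS2 2.1.2, and the builds hg19 and GRCh37, are named per the submitters' processing notes, with no role or order. MACS2 is a peak caller. Read trimming, mapping filters, removal of duplicates and any shift of reads to the transposase cut site are not given in the sources used here. Each deposited list gives, per peak, a score, a fold enrichment, a −log10 p, a −log10 q and the summit offset. The deposited fold is the ratio of summit tags to the caller's background, each with 1 added, as shown by the recovery described next. The score deposited by the authors is the whole part of 10 times the −log10 q, in all rows but 3. The smallest −log10 q was 1.31 and 1.30, so both lists stop at q of 0.05. Scores, folds and −log10 values describe, rank or filter peaks of their own list, and fold and −log10 p also gave the summit tags that were compared between lists. A −log10 q of at least 5 was applied to each list by its own values, which depend on depth, so counts at that level are not a like-for-like comparison. No list holds the same interval more than once, and peaks of a list do not overlap each other.

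Tags at each summit were recovered from the fold and the −log10 p of the deposited lists. In this caller p is the Poisson probability of more than the observed tags at the background, so fold and p together give a whole number of tags and the background. A whole number matched the printed −log10 p within 0.001 for 100% of the 194551 vehicle rows and 100% of the 163735 GSK2879552 rows. Simulated peaks with known tags (5000 of them), made with the same formulas, were recovered in 100% of cases, which checks the inversion only. Backgrounds above the lowest value were multiples of 0.01 within 0.001 in 100% of rows of both lists, the step that tags of 100 bp counted over 10 kb give, and no peak was narrower than 100 bp. The lowest background is the genome-wide one, which is proportional to the number of tags, and the ratio of both, 1.18, was used to scale tags for depth. That background held for 40.3% of vehicle rows and 38.5% of GSK2879552 rows. No summit had more than 199 tags, under the limit of 200 that 1 tag per position and strand allows. The highest summits may therefore be compressed in both lists.

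Peaks on chromosomes 1 to 22, X and Y were compared. The 2646 vehicle and 2200 GSK2879552 peaks on other sequences (1.36% and 1.34%) were left out of the comparisons. Those sequences include alternative haplotypes that repeat parts of the main chromosomes, so tags in such parts may be split. Peaks were shared at 1 bp of overlap. Shares have exact Clopper-Pearson 95% intervals over peaks, tag numbers have exact Poisson intervals, and tag ratios have exact binomial intervals. All of them cover counting error only. Neighbouring positions share tags, and no interval measures the spread between cultures. Chance overlap was described by 100 circular shifts within each chromosome.

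The design, the alternatives and the rules for named regions were fixed before the data were examined, except where stated. That plan included promoter classes, transcription factor motifs and gene lists. These need an annotation and a genome of the hg19 build. The gene table at hand is of another build, so they were not analysed here. Of the naming rule, the 10 strongest peaks in 1 list only per direction were kept, without the restriction to regions distal to genes. The tag recovery, the paired peaks, the 1 Mb windows and the rule for naming windows and pairs (the 5 highest and 5 lowest, pairs with at least 100 tags, of which the text gives some) were chosen after the lists were seen. The alternatives were a reciprocal overlap of 50%, summits within 250 bp, a −log10 q of at least 5, lists of equal length, every row and all sequences. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.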

Results

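Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in LNCaP cells. LNCaP is an androgen-sensitive human prostate cancer line. Cells received vehicle or GSK2879552, an inhibitor of the histone demethylase LSD1 (KDM1A). The labels give 50 µM for 4 hours in medium with 5% CSS. They also give 10% fetal serum for all 4 samples. Each condition was represented by 2 sequencing lanes, labelled as technical replicates, and by 1 peak list that the labels of both lanes name. The comparison therefore had 1 library per condition and no replicate check, and it describes these libraries. No test between conditions was possible, and the intervals below cover counting error only. Positions are 1-based hg19 coordinates. No gene positions in that build were used here, so regions are named by coordinates and not by gene.

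Fewer and narrower regions were listed as open after GSK2879552. On chromosomes 1 to 22, X and Y, the vehicle list held 191905 peaks and the GSK2879552 list 161535 peaks, which is 15.8% fewer. The peaks covered 49.6 Mb in the vehicle list and 37.3 Mb in the GSK2879552 list, which is 24.9% less. The median peak width was 189 bp (interquartile range 133 to 293) with vehicle and 171 bp (125 to 257) with GSK2879552. Regions of at least 500 bp numbered 18050, or 9.41% of the vehicle list, against 11846, or 7.33% of the GSK2879552 list.

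The gap was wider among peaks that passed a stricter level of their own list. At a −log10 q of at least 5, a value that depends on depth, 143829 peaks remained in the vehicle list and 101402 in the GSK2879552 list, a ratio of 0.705 where the full lists gave 0.842. Within the vehicle list the authors' median fold enrichment at the summit was 5.44 (interquartile range 3.96 to 8.02). Within the GSK2879552 list it was 4.34 (3.50 to 6.19). These folds are the authors' own values, each relative to the background of its own library.

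The library behind the shorter list was the deeper one. The genome-wide background, in tags expected at any position, was 2.31 for vehicle and 2.72 for GSK2879552, so the GSK2879552 library held 17.6% more tags if both lists were made with the same tag length and genome size. The total number of tags per library is not given in the sources used here. The smallest number of tags at a listed summit was 8 in the vehicle list and 9 in the GSK2879552 list.

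Nearly all strong regions were listed under both conditions, and the lists differed mainly among weak peaks. Of the vehicle peaks, 118082 overlapped a GSK2879552 peak by at least 1 bp, a share of 61.5% (exact 95% binomial interval 61.3 to 61.7). Of the GSK2879552 peaks, 123495 overlapped a vehicle peak, a share of 76.5% (76.2 to 76.7). When one list was shifted along each chromosome 100 times, at most 2.67% of vehicle peaks and 3.19% of GSK2879552 peaks overlapped. Peaks in the weakest decile of the vehicle list by −log10 p were shared in 19.0% of cases (18.5 to 19.6), and those in its strongest decile in 100% (99.98 to 100). In the GSK2879552 list the weakest decile was shared in 26.4% of cases (25.7 to 27.1), and its strongest decile also in 100%. Of the vehicle regions of at least 500 bp, 99.7% overlapped a GSK2879552 peak, while of those under 200 bp 37.8% did. In the GSK2879552 list these shares were 99.4% and 66.4%.

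**Figure D1:**
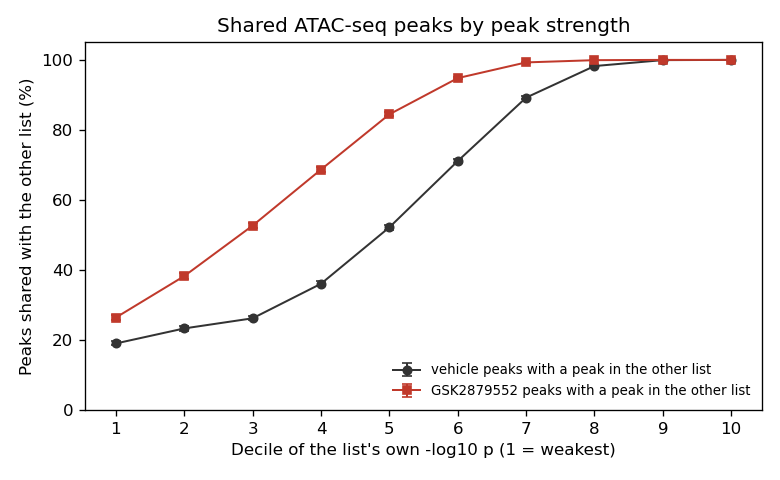
Share of peaks that overlap a peak of the other list (percent, vertical axis) by decile of the list's own −log10 p (horizontal axis, 1 is weakest), for vehicle (black circles) and GSK2879552 (red squares), with exact 95% binomial intervals. The vehicle share goes from 19.0% in the weakest decile to 100% in the strongest, and the GSK2879552 share starts at 26.4%.

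Regions listed under 1 condition only carried more tags in the vehicle list. The 73823 vehicle-only peaks had a median of 15 tags at the summit, and 49.1% of them reached a −log10 q of 5 in their own list. The 38040 GSK2879552-only peaks had a median of 13 tags, and 12.1% reached that level in theirs. Among the top 25% of each list by −log10 p, 76 of 47976 vehicle peaks and 2 of 40383 GSK2879552 peaks had no overlapping partner. With a reciprocal overlap of 50% these counts were 3500 and 3194. Under a rule that asks for summits within 250 bp they were 607 and 1152, so their order turned. Of these, 531 and 1151 did overlap a peak of the other list, with a summit farther away.

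The 10 strongest vehicle-only regions carried 35 to 43 tags at the summit, and the nearest GSK2879552 peak lay 681 to 13999 bp away. The first was chromosome 1, positions 88216453 to 88216679, with 40 tags (exact 95% Poisson interval 28.6 to 54.5) over a background of 2.31. The nearest GSK2879552 peak lay 13999 bp away. Chromosome 20, 44221306 to 44221502, also carried 40 tags, with the nearest GSK2879552 peak at 7470 bp. There were 37 tags at chromosome 14, 79157621 to 79157810, and the region on chromosome 2, 148272886 to 148273065, carried 36 tags. Chromosome 9 held 2 of the regions, with 37 tags at 2872649 to 2872839 and 38 tags at 95719590 to 95719731. Next, chromosome 16, 67294631 to 67294887, had 43 tags over a background of 3.96. Regions on chromosome 11, 83447812 to 83447978, and chromosome 8, 15095829 to 15096030, had 35 tags each. The list closed with chromosome 10, 79606515 to 79606871, with 43 tags over a background of 4.22. For the first region, the same share of tags would be 47.0 tags at the depth of the GSK2879552 library. The tags at these positions in that library are not given by its list.

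The 10 strongest GSK2879552-only regions lay on higher local background, from 3.05 to 14.95 tags, and 6 of them had a vehicle peak within 600 bp. The first was chromosome 13, 36532082 to 36532413, with 36 tags (25.2 to 49.8) over a background of 5.11, and a vehicle peak lay 758 bp away. Chromosome 2, 242838656 to 242838909, had 40 tags over 7.18, with a vehicle peak 38 bp away. On chromosome Y, 13663785 to 13663915 had 26 tags, and the region on chromosome 4, 151172150 to 151172278, had 29 tags. On chromosome 1, 55 tags were found at 121354980 to 121355092 over a background of 14.95, with 28 tags at 20200542 to 20200664 and 33 tags at 246948927 to 246949063. On chromosome 16, 47 tags were found at 1235610 to 1235773 and 36 tags at 90184593 to 90184752. On chromosome 5, 69755130 to 69755256 had 31 tags. Among the vehicle-only regions above, backgrounds went from 2.31 to 4.22, and 6 of those 10 stood at the genome-wide level. This contrast holds for the 10 strongest regions per direction, and the full sets differed little. Over 5 Mb from the outermost listed peaks of a chromosome, 18283 of 32756 GSK2879552-only and 38773 of 66416 vehicle-only peaks stood at that level. Nearer to them the counts were 1315 of 5284 and 1852 of 7407.

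Where both lists held a peak, the GSK2879552 library had fewer tags at the summit. Among 110134 peaks that overlapped exactly 1 peak of the other list, the median was 31 tags with vehicle and 23 tags with GSK2879552, and 83.3% had fewer tags with GSK2879552 before any scaling. After scaling by the genome-wide background, the median log2 ratio of GSK2879552 to vehicle was -0.56 (interquartile range -0.75 to -0.36), a ratio of 0.680. Summed over all pairs, 3247960 tags against 4046751 tags gave a scaled ratio of 0.683 (exact binomial interval 0.682 to 0.684), and 0.803 without scaling. The median log2 ratio was -0.23 for pairs with under 30 tags over both lists, which lie near the listing threshold. It was -0.65 for pairs with 40 to 60 tags and -0.49 for pairs with 120 to 200 tags.

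Of the 18448 pairs with at least 100 tags over both lists, 150, or 0.813%, had a scaled ratio above 1. In 45, or 0.244%, the scaled log2 ratio was below -1. Scaling matters here, since among pairs with 120 to 200 tags 99.1% were lower with GSK2879552 after it and 94.9% before it. The lowest ratio, 0.419 (0.267 to 0.645), was at chromosome 18, 45557445 to 45557817, with 67 vehicle and 33 GSK2879552 tags. Next came chromosome 5, 117866909 to 117867427, with 0.425 (0.273 to 0.651), and chromosome 2, 37048276 to 37048743, with 0.444 (0.288 to 0.673). The highest ratio, 1.35 (0.935 to 1.98), was at chromosome 1, 2584748 to 2584961, with 49 vehicle and 78 GSK2879552 tags over backgrounds of 26.4 and 31.0. Chromosome Y, 58917178 to 58917597, followed with 1.31 (0.887 to 1.97). Chromosome 2, 5162691 to 5163029, had 1.30 (0.865 to 1.96) over the low vehicle background of 2.31. The intervals of these 3 highest regions include 1, but they lie above 0.683, the ratio summed over all pairs. Those of the 3 lowest regions lie below 0.683. Regions picked as the most extreme of many are partly extreme by counting error.

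After scaling for depth, lower tags at paired peaks were found along every chromosome. Of 2342 windows of 1 Mb with at least 20 paired peaks, all 2342 had a scaled ratio of summed tags below 1, and in 2332 the exact interval lay below 1. The median window was at 0.675, with 0.631 at the 5th and 0.728 at the 95th percentile. The lowest window was chromosome 2, 84 to 85 Mb, at 0.584 (0.522 to 0.654), followed by chromosome 1, 56 to 57 Mb, at 0.586 (0.535 to 0.643). The highest were chromosome 10, 39 to 40 Mb, at 0.982 (0.885 to 1.09) and chromosome 8, 46 to 47 Mb, at 0.981 (0.898 to 1.07). They were followed by chromosome Y, 58 to 59 Mb, at 0.974 (0.928 to 1.02) and 28 to 29 Mb, at 0.955 (0.881 to 1.04), and by chromosome 7, 61 to 62 Mb, at 0.948 (0.881 to 1.02). Before scaling, these 5 highest windows held more GSK2879552 than vehicle tags, for example 792 against 686 on chromosome 10. In 2163 windows vehicle-only peaks outnumbered GSK2879552-only peaks, and in 150 the order was the opposite.

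**Figure D2:**
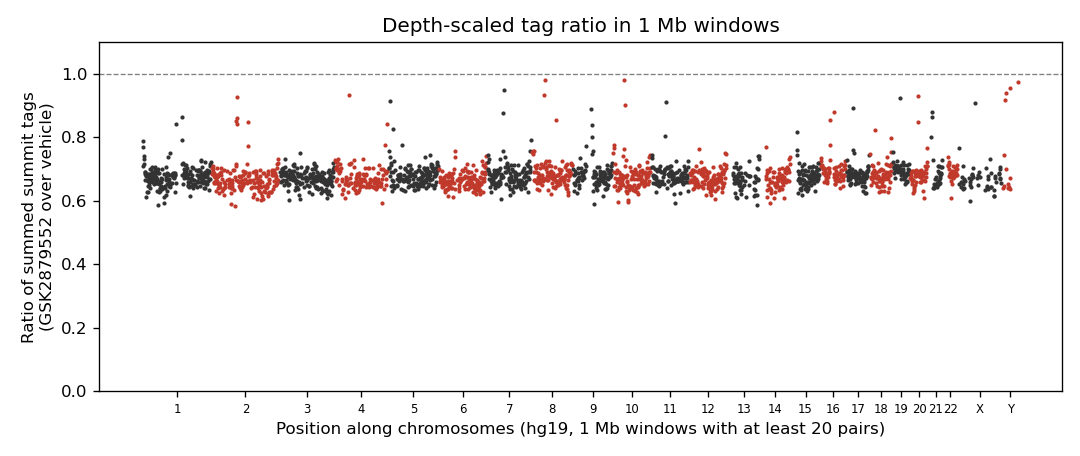
Ratio of summed summit tags, GSK2879552 over vehicle and scaled for depth (vertical axis), in 1 Mb windows with at least 20 paired peaks along the chromosomes (horizontal axis, hg19; colours alternate between chromosomes). All 2342 windows lie below 1 (dashed line), most between 0.631 and 0.728, and a few near 1.

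Between chromosomes the tag ratio at paired peaks varied little, while the number of listed peaks varied more. The median log2 ratio ranged from -0.58 on chromosome 6 to -0.52 on chromosome 16 among the 22 autosomes. It was -0.57 on chromosome X and -0.36 on chromosome Y. The number of GSK2879552 peaks per vehicle peak was 0.760 on chromosome 2 and 0.801 to 0.902 on the other autosomes. It was 0.671 on chromosome X, with 3352 against 4999 peaks, and 0.761 on chromosome Y. GSK2879552-only peaks made up 10.8% of the GSK2879552 list on chromosome X (exact interval 9.80 to 11.9), against 17.2% to 28.8% on the autosomes. With the deciles of peak strength weighted alike, this share was 14.0% on chromosome X, 19.6% on chromosome 2 and 20.3% to 26.1% on the other autosomes. The share of vehicle peaks with a GSK2879552 partner was 56.6% on chromosome X (55.2 to 58.0) and ranged from 58.3% on chromosome 13 to 69.3% on chromosome 19 among the autosomes. With the deciles of peak strength weighted alike, this share was 60.2% to 63.2% on the autosomes, 59.4% on chromosome X and 66.0% on chromosome Y. Chromosome X also had the most GSK2879552 peaks at the genome-wide background, 67.1%. On the autosomes this went from 9.44% on chromosome 22 to 56.1% on chromosome 4. Whether it bears on the counts of chromosome X was not tested.

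**Figure D3:**
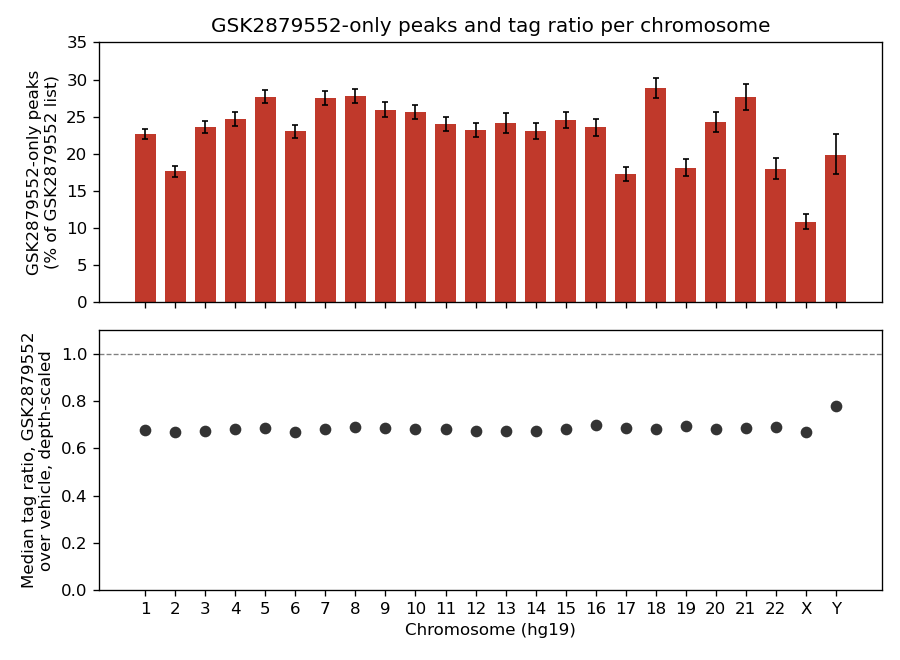
Upper panel, GSK2879552-only peaks as a percentage of the GSK2879552 list on each chromosome, with exact 95% binomial intervals; lower panel, median depth-scaled ratio of summit tags at paired peaks. Chromosome X has the lowest share of GSK2879552-only peaks, 10.8%, while its tag ratio lies with those of the autosomes; chromosome Y has the highest tag ratio.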

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

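The tests on depth, on the limit of tags per position and on the uniformity of the ratio were chosen after the results were seen. More peaks than in the vehicle list were found in 2 places outside the compared chromosomes. The GSK2879552 list held 1171 peaks on unplaced and random contigs, against 1104 in the vehicle list, where the compared chromosomes had fewer. After scaling for depth, tags at the paired peaks of these contigs were lower than with vehicle, with a median log2 ratio of -0.19. That direction rests on the scaling, since unscaled the median pair had slightly more tags with GSK2879552. On mitochondrial DNA the GSK2879552 list held 6 peaks against 5, with up to 199 and 197 tags. This is next to the limit of 200, so tag numbers there carry no information on amount. On alternative haplotypes the order was that of the main chromosomes, with 1023 against 1537 peaks.

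The GSK2879552 list was shorter, and its paired peaks had fewer tags. A lower depth of the GSK2879552 library is argued against, since its genome-wide background was 1.18 times that of vehicle. The limit of 1 tag per position and strand is argued against as a source of the lower tags at paired peaks as a set. Corrected for that limit, their median log2 ratio was -0.59, lower than the -0.56 without the correction. Pairs with 40 to 60 tags over both lists, far below the limit, had a median log2 ratio of -0.65. A lower share of tags in open chromatin across the whole GSK2879552 library, for example from a less efficient tagmentation, stays open. The autosome medians differed by at most 0.063 on the log2 scale, but by 0.220 with chromosome Y, at -0.36, included. The ratio was not uniform within chromosome Y. Its windows at 28 to 29 and 58 to 59 Mb, beside its longest stretch without a listed peak, were at 0.955 and 0.974. Several other windows of chromosome Y lay below 0.675, the median of all windows. The 2 windows at 28 to 29 and 58 to 59 Mb held 35 and 44 of the 678 pairs of chromosome Y, a small part. Where its other pairs with a higher ratio lie was not tested. The median of chromosome Y shows neither that the whole chromosome departed from the autosomes nor that the departure was confined to these windows. With 1 library per condition a library-wide difference cannot be told apart from a genome-wide effect of the treatment, which stays open as untested.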

How the results depend on the processing

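With 1 library per condition no replicate could be left out. No paired analysis was possible, since each condition had 1 library and its lanes are technical replicates. Promoter, motif and gene list alternatives were not run, for want of an hg19 annotation. The alternatives for the top 25% and for tag ratios, apart from the overlap rules themselves, were chosen after the data were seen. The cause of the changes below was not tested, except where the construction of the alternative shows it. The share of vehicle peaks with a GSK2879552 partner, 61.5%, was 52.9% with a reciprocal overlap of 50%, 61.9% with summits within 250 bp, 63.2% at a −log10 q of at least 5 in both lists and 69.3% with lists of equal length. The reverse share, 76.5%, was 62.8%, 73.6%, 92.7% and 72.8% under the same alternatives. The first 3 of these alternatives keep lists of unequal length, in which a share depends on the lengths of both lists. With lists of equal length the shares differed by less, 69.3% against 72.8%. The count of unpartnered vehicle peaks in the top 25%, 76, was 3500, 607, 27 and 18 under these alternatives. That of GSK2879552 peaks, 2, was 3194, 1152 and 0, and it was 2 with lists of equal length. Stricter overlap rules count regions that overlap but differ in width or summit. The number of GSK2879552 peaks, 161535, was 101402 at a −log10 q of at least 5. Counting every row is the same analysis, since no interval was listed more than once. Counting all sequences kept both shares within their intervals and every count within 1.5 times. The median log2 ratio of summit tags, -0.56, was -0.32 with no scaling for depth, -0.61 with the background subtracted and -0.59 when corrected for 1 tag per position and strand. It was -0.56 for pairs with at least 60 tags and -0.56 at a −log10 q of at least 5, both a little lower than for all pairs. It stayed below 0 in all 6 alternatives run. What depth limits was not tested, as no list was called at another depth. No listed summit had under 8 tags with vehicle or under 9 tags with GSK2879552.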

Other observations

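The tests of the contigs and of the chromosome ends were chosen before their values were seen, and the test of the listing threshold, the splits by other widths and by summed tags, and the count of windows beside peak-free stretches after. The 5 highest of the 1 Mb windows, on chromosomes 7, 8, 10 and Y, all touched the longest stretch of their chromosome without any listed peak. No hg19 sequence was used here, so a stretch without listed peaks is not shown to be closed chromatin. Their scaled ratios were 0.948 to 0.982, while the median of all windows was at 0.675. Over all chromosomes, 30 windows with at least 20 pairs touched such a stretch, on 21 chromosomes, with a median ratio of 0.880. They include the 5 highest windows, which prompted the count. Of the 30 windows, 25 lay above 0.728, the 95th percentile of all windows. The other 5 lay between the 5th and the 95th percentile, among them chromosome 3 at 93 to 94 Mb with 0.693 and chromosome 19 at 24 to 25 Mb with 0.691. Peaks in 1 list only had no common order in the 5 highest windows: GSK2879552-only peaks outnumbered vehicle-only peaks on chromosomes 7 (34 against 14), 8 (12 against 6) and 10 (12 against 8), and the order was the opposite in both windows of chromosome Y (11 against 17 and 7 against 24).

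Pairs on high local background had a ratio somewhat nearer to 1. Among pairs with at least 60 tags, the 6893 pairs with a background at least 4 times the genome-wide one had a median log2 ratio of -0.48, against -0.58 for the other 41619 pairs. Summit tags include the background, and with it subtracted the medians were -0.50 and -0.62. The former pairs also had more tags, with a median of 66 vehicle tags against 48, and the difference was smaller among pairs with at least 80 summed tags. At like summed tags the medians were -0.53 and -0.64 for 60 to 80 tags, -0.53 and -0.59 for 80 to 120, -0.46 and -0.50 for 120 to 200, and -0.39 and -0.41 for 200 to 400. With the background subtracted as well, they were -0.59 and -0.71 for 60 to 80 tags and -0.40 and -0.42 for 200 to 400. Split further by a vehicle peak under 150 bp, the median on high background was -0.29 for 626 narrow pairs and -0.49 for 6267 wider pairs, and on lower background -0.46 for 612 narrow and -0.58 for 41007 wider pairs. The vehicle width depends on vehicle tags, so this split favours pairs with few vehicle tags. With narrow pairs taken by the GSK2879552 width, which favours pairs with few GSK2879552 tags, the order on high background turned, with -0.51 for narrow and -0.48 for wider pairs. The order was kept with both peaks narrow, at -0.33 for 515 narrow pairs and -0.49 for wider pairs. By the mean width it was also kept, at -0.43 and -0.48, where the difference was smaller. On lower background the order turned by the GSK2879552 width, with -0.66 for narrow and -0.57 for wider pairs. There it also turned by the mean width, at -0.60 and -0.58, and was kept with both peaks narrow, at -0.49 and -0.58.

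For what remains of the difference with background, a candidate explanation is that tags there are set by repeats or DNA copies and not by openness. Unplaced and random contigs, which had no part in the pattern, had a median log2 ratio of -0.19 over 751 pairs, while alternative haplotypes had -0.66 over 841 pairs. The contig value lies above a bound of -0.3, which was set for narrow pairs on high background and not for this difference. The contigs themselves had a higher median vehicle background, 6.4 against 2.31 on alternative haplotypes, so they cannot separate repeats from background. Selection by the listing threshold stays open, since a peak on high background needs more tags to be listed. Its test rests on the narrow pairs by vehicle width. Their median of -0.29 (95% interval over pairs and not over cultures, -0.34 to -0.23) is partly set by that choice.

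GSK2879552-only peaks were more frequent near chromosome ends, taken as the first and last listed peak of each chromosome. A first listed peak need not lie near the start of its chromosome, so these ends can include other regions. Within 5 Mb of the first or last listed peak of a chromosome there were 0.366 GSK2879552-only peaks per shared peak, against 0.3003 elsewhere, a ratio of 1.22, with the ends higher on 18 of 24 chromosomes. For vehicle-only peaks the same ratio was 0.854, but it was 1.06 among peaks at the genome-wide background and 1.16 above it. A higher local background near the ends is argued against as the source, since among peaks at the genome-wide background the ratio for GSK2879552-only peaks was 1.73, and above that background 1.47. A difference in base composition between the libraries was not tested, since no hg19 sequence was used here. The treatment stays open too, as 1 library per condition does not separate it from the library. Paired peaks had a median log2 ratio of -0.50 near the ends and -0.56 elsewhere.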
